A study of Drosophila melanogaster with 10 samples.

How the data were processed

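Total RNA of whole flies was hybridised to an Affymetrix Drosophila array by a core facility after extraction with Trizol, per the labels. The authors normalized the arrays with dChip, which finds a set of probes of stable rank and draws the normalization curve through it, per the labels. The version, and whether the expression index used the mismatch probes, are not given in the sources used here. The deposited values are intensities on a linear scale, since all lie above 0 and the array maxima lie between 8685 and 10406. A microarray intensity is relative: it compares 1 probe set between arrays and not 2 probe sets with each other. Because the authors scaled the arrays to each other, a change shared by most transcripts would be removed. The table holds 14010 probe sets on 10 arrays, with 0 missing values and 0 columns left unused.

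Of these, 44 were control probe sets. Among the other 13966, the platform annotation given here named 1 gene for 12443, several genes for 327 and none for 1196, which are unnamed here. Symbols were looked up by Entrez identifier in the gene table of the Release 6 assembly, which held 12394 of them, and 49 were kept as annotated. This gave 10844 different genes. No gene was named from a probe set with several. The files name no genome build, so no coordinates are given.

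Intensities under the 20th percentile of all values, 57.2, were set to it before taking log2. Fold changes on this scale understate the change of dim transcripts. Probe sets whose mean log2 lay at or above the 40th percentile were tested, 8380 in all. Each fit used limma (lmFit, then eBayes with an intensity trend) with Benjamini-Hochberg adjustment at 0.05, two-sided. The trend was the slope on the hour, printed as the fitted change over the 11 hours from hour 1 to hour 12. The other fits were hours 7 to 12 against hours 1 to 6 and a natural cubic spline of the hour with 3 degrees of freedom. Breaks that left at least 2 arrays a side were fitted one at a time. Gene lists used the brightest probe set of each gene and limma's camera with a preset correlation of 0.01, with the estimated correlation and fry beside it. 4 lists had fewer than 3 tested genes. Array distance and control ratios used 100000 permutations.

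The sample groups, the tests, the gene and marker lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named every probe set with a single gene that passed the trend, then those with the smallest p up to 5 a direction, given as values. It added the 10 smallest p-values of the smooth test not yet named, the 5 largest folds each way of later against earlier hours among those that passed, up to 4 members of each reported list with the smallest trend p, and a fixed set of clock, insulin and lipid genes. Other genes named were chosen after their values were seen: the genes at single hours, and Arr2, trp and inaC. 2 or more probe sets of a gene were tested separately. tim had 2 further probe sets under the brightness limit, with means of 14.1 and 71.

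The trend, later against earlier and spline fits were first tested on simulated data, with 8380 probe sets and 200 of them changed. The simulated values had the real means and the real spread about the linear fit. The planted change was a straight line, a step or a quadratic curve, to match each fit, so the fits are not compared with each other. With a total change of 1.1 on the log2 scale the trend fit recovered 94%, the later against earlier fit 97% and the spline fit 87.5%. With 0.55 they recovered 55.5%, 87.5% and 21%. With 2.2 they recovered 99%, 100% and 98.5%. Calls outside the changed probe sets made up between 2.46% and 10.3% of all calls. By camera with the preset correlation, simulated arrays without a shift gave 0 called lists in 20 sets, and a shifted list was called in 20 of 20. These simulations drew genes independently, which real arrays do not do. With fewer than 200 changed probe sets the Benjamini-Hochberg adjustment is stricter, so these percentages can overstate recovery in the real data. Other breaks, other curves, the estimated correlation and fry were not simulated.

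The rank correlation took its p from the exact distribution over all orders of 10 ranks. Alternatives were quantile normalization, median centring, a floor at the 5th percentile (27), an added offset in place of a floor, no filter or a filter at the 60th percentile, other variance models, 1 probe set per gene, the actin ratio as a covariate, array order in place of the hour, unmoderated least squares, an exact rank correlation, other splits and curves, and leaving out each array. Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.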

Results

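RNA from whole Drosophila melanogaster was measured on 10 Affymetrix arrays, with 1 array per hour at hours 1, 2, 3, 5, 6, 7, 9, 10, 11 and 12 of a 12 hour course. Per the labels, hours 4 and 8 yielded too little RNA. The animals had been moved to food without yeast early in the third larval instar and stayed on it. The course began 4 days after the adults emerged. Flies returned to yeast and samples taken before the course were part of the study and were not used here. All 10 arrays belong to the yeast-free group, so the hour was the factor compared. The labels name change-point analysis over ordered samples and the key terms insulin, diet and nutrition. The table held 14010 probe sets, of which 8380 were bright enough to test, and they covered 6822 named genes. Array medians lay between 111.1 and 120 intensity units. There was no second array at any hour and the labels do not say how many flies were pooled. Each limma p-value of a probe set therefore rests on the scatter of single arrays about a fitted course. The camera p-values set the slopes of a list against those of the other genes, with the preset correlation unless stated. For array distance and control ratios the p-values come from permutation. The number of arrays limits the precision.

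The first comparison asked which transcripts had a linear trend over the course. 4 probe sets had one, and 2 were higher and 2 lower later in the course. Pdh, which encodes a retinol dehydrogenase of retinal pigment cells, fell by 1.66 ± 0.21 on the log2 scale from hour 1 to hour 12 (SE, n = 10 arrays; limma, adjusted p = 0.0432). Its intensity was 324.3 at hour 1 and 94.6 at hour 12. The gene t, known as tan, encodes an enzyme that frees histamine and dopamine from their beta-alanyl conjugates. It fell by 0.90 ± 0.13 (adjusted p = 0.0458), from 231.4 to 119.1. The clock repressor gene vri rose by 0.98 ± 0.14 (adjusted p = 0.0458), from 243.4 to 425.8. Usp8, a deubiquitinase gene that also carries the name CG5798, rose by 0.72 ± 0.10 (adjusted p = 0.0458), from 96 to 144.2. A linear trend need not be a steady course. Usp8 lay between 91.1 and 96 up to hour 5, and vri between 208 and 267.9 up to hour 7.

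Other named genes with small p-values did not pass, and their values were as follows. The phototransduction channel gene trpl had a fitted change of 1.12 ± 0.18 (limma, adjusted p = 0.098), with 468.6 at hour 1 and 842.9 at hour 12. PIP82, which encodes a photoreceptor phosphoprotein, had 0.42 ± 0.10 (adjusted p = 0.584), and the arrestin gene Arr1 had 0.40 ± 0.10 (adjusted p = 0.604). CG17108 had -1.55 ± 0.26 (adjusted p = 0.109), CG7300 had -0.98 ± 0.18 (adjusted p = 0.178) and Send1, a spermathecal gland protease gene, had -1.04 ± 0.22 (adjusted p = 0.418). Over all tested probe sets 311 had an unadjusted p under 0.05, where chance alone would give 419. The count of 4 became 0 without the array of hour 5, 6, 7, 9, 10 or 12, 1 without that of hour 2 or 11, and 2 without that of hour 1 or 3. It also became 0 with no filter on dim probe sets, with the actin 3' to 5' ratio as a covariate, with unmoderated least squares and with rank correlation. With quantile normalization it was 5, where trpl and CG17108 also passed and t did not.

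The second comparison set the 5 arrays of hours 7 to 12 against the 5 arrays of hours 1 to 6. CG17108 was the 1 gene that differed. Its mean intensity was 888 ± 136.8 (SD, n = 5) in the later hours and 1899 ± 336.5 (SD, n = 5) in the earlier ones, a difference of -1.09 ± 0.13 on the log2 scale (SE; limma, adjusted p = 0.0341). All 5 later values, 732 to 1041, lay below all 5 earlier values, 1509 to 2425. Pdh had a difference of -1.09 ± 0.15 (limma, adjusted p = 0.0607). Nplp2, a neuropeptide-like precursor gene, had -0.76 ± 0.11 (limma, adjusted p = 0.0617), with means of 1538 ± 183.5 and 2614 ± 387.2. Col4a1, a basement membrane collagen gene, had -0.49 ± 0.09 (limma, adjusted p = 0.178). Unadjusted p-values under 0.05 numbered 524. The count of 1 became 0 without the array of hour 1, 2, 6, 9, 10, 11 or 12 and 2 without that of hour 3, 5 or 7. It was 0 when the course was split after hour 5 or after hour 7. With quantile normalization or a stricter filter on dim probe sets Pdh and Nplp2 also passed.

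A scan over single breaks in the course asked whether one time point divided the arrays. A break after hour 3 gave 1 probe set, Send1, with 212.8 to 226.5 in hours 1 to 3 and 105.4 to 125.8 from hour 5 on. A break after hour 6 gave 1 probe set, CG17108. The breaks after hours 3 and 6 had 619 and 524 probe sets at an unadjusted p under 0.05 by limma, where chance alone would give 419. Only 3 arrays lay before the break after hour 3, that of hour 3 among them. Each break was adjusted on its own, without allowance for the number of breaks. Breaks after hours 2, 5, 7, 9 and 10 gave 0 by limma, with 136, 268, 377, 265 and 187 probe sets at an unadjusted p under 0.05. With quantile normalization the break after hour 6 gave 3.

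The third comparison looked for any smooth course over the hours, including a fall followed by a rise. By a limma F test over a spline, 0 probe sets passed, 136 had an unadjusted p under 0.05, and the smallest adjusted p was 0.161. The clock gene tim was among those with the smallest p-values. Its intensity was 636.2 at hour 1, 250.7 at hour 7 and 785.8 at hour 12 (limma, adjusted p = 0.161), a ratio of 3.13 between the highest and lowest array. CG3739 went from 225.4 at hour 1 to 109.7 at hour 6 and 138.1 at hour 12 (limma, adjusted p = 0.161). LManVI, a lysosomal mannosidase gene, had 165.4 at hour 1 and 86 at hour 12 (limma, adjusted p = 0.632). CG17560 and CG17562, genes of the fatty acyl-CoA reductase family, had their highest values at hours 7 and 6, 924.8 and 205.4. Further genes named by p-value were CG13309, Ugt35B1 and Obp99c, whose limma adjusted p-values were 0.768, 0.9999 and 0.9999. A curve with fewer terms changed the calls. A quadratic curve gave 4 probe sets, Usp8, tim, vri and CG3739, each with a limma adjusted p of 0.0336. A 24 hour cosine and sine gave 6, those 4 together with Send1 and Pdh.

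**Figure D1:**
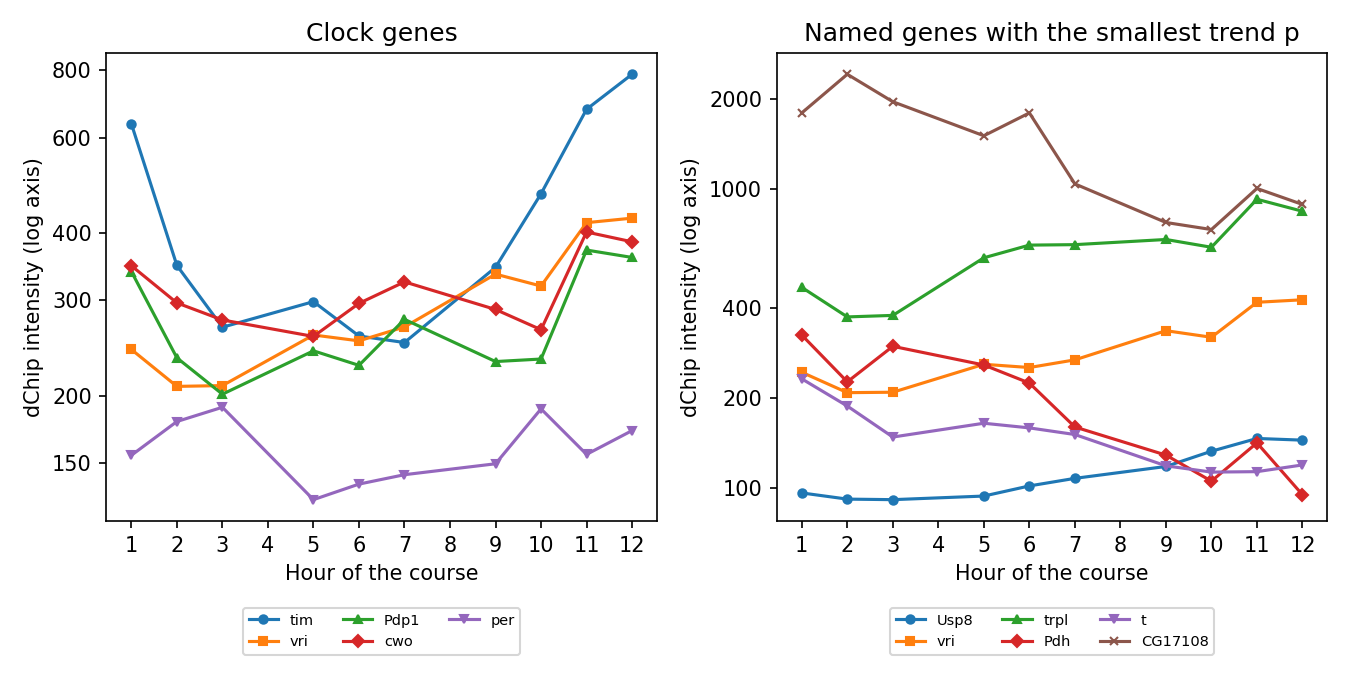
Intensity per array (log axis) against the hour of the course, with 1 array per hour and no error bars because no hour has a second array; lines join the arrays of each gene. In the left panel tim is lowest at hour 7 (250.7) and highest at hour 12 (785.8), and in the right panel Pdh goes from 324.3 to 94.6 while vri goes from 243.4 to 425.8.

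Gene lists fixed in advance were then set against the slope over the hours, 32 of them with at least 3 tested genes. By limma's camera test with a preset correlation between genes, 7 lists moved. None of the 7 held with a correlation estimated from the arrays or with the fry test, where the smallest adjusted p was 0.414 and 0.357. As many lists were called in 18 of 100 orders of the hours, the real order among them, so the list calls below carry that limit. Adjustment over a list alone, used below for single members, makes no allowance for the 32 lists.

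The yolk protein genes Yp1, Yp2 and Yp3, made by the female fat body and ovarian follicle cells, moved down together. The list's median change from hour 1 to hour 12 was -1.84 on the log2 scale (camera, adjusted p = 9.17e-05; adjusted p = 0.414 with an estimated correlation). Over all probe sets 0 of 3 passed, and adjusted over the list alone 3 of 3 fell, each with a limma adjusted p of 0.00465. The estimated correlation between these genes was 0.905, so the 3 calls are not independent. Yp1 had an intensity of 1332 at hour 1, 734.7 at hour 6 and 161.7 at hour 12. Yp2 had 1135, 509.3 and 166 at the same hours, and Yp3 had 1072, 943.1 and 327.9. The fall was not steady, since all 3 genes were lower at hour 5 than at hour 6. Without the array of hour 1 the median change was -1.26, and all 3 still passed over the list alone. Among the other female markers, 0 of 8 eggshell genes and 0 of 8 female germline genes passed over all probe sets or adjusted over the list alone. Their lists had camera adjusted p-values of 0.7 and 0.589. Vm26Aa, a vitelline membrane gene, had 1002 at hour 1, 782 at hour 3 and 333.8 at hour 12 (limma, adjusted p = 0.937).

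Clock genes driven through the E-box had an upward slope, with a list median of 0.33 (camera, adjusted p = 0.000105, and adjusted p = 0.414 with an estimated correlation). 5 of 5 slopes were positive. The course was a fall and then a rise. Relative to each gene's mean, the list stood at 0.186 at hour 1, -0.266 at hour 3, -0.26 at hour 6 and 0.486 at hour 12. vri passed over all probe sets, and adjusted over the list alone it was the 1 of 5 with a trend, while vri and tim were the 2 of 5 with a smooth change. Pdp1 had 339.2 at hour 1, 201.2 at hour 3 and 371.7 at hour 11. The clockwork orange gene cwo had 347.7, 276 and 401.4 at those hours. Neither passed, and per, with 155.1 at hour 1 and 172.3 at hour 12, had a change of 0.01 ± 0.18 (limma, adjusted p = 0.994). The smooth count over the list alone was 4 without the array of hour 10. The list median was 0.15 without the array of hour 12 and 0.69 without that of hour 1. The light receptor gene cry had a change of 0.06 ± 0.16 (limma, adjusted p = 0.97). Clk was too dim to test, with 78.8 at hour 1 and 47.2 at hour 12. The clock output gene to and the translation repressor gene Thor were named by no probe set here.

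Clock-controlled outputs had 4 tested genes and a median change of 0.18 (camera, adjusted p = 0.0296; adjusted p = 0.414 with an estimated correlation). Usp8 rose over all probe sets and over the list alone. Jhbp13, a gene of the juvenile hormone binding protein family also named CG5945, fell over the list alone (adjusted p = 0.0199), with a highest value of 484.6 at hour 3 and a lowest of 192.4 at hour 10. Slob, a potassium channel binding protein gene, had 0.30 ± 0.14 (limma, adjusted p over the list alone = 0.0652) and CG2121 had 0.06 ± 0.14 (limma, adjusted p over the list alone = 0.705). Without the array of hour 12 the list median was 0.09 and the trend calls over the list alone went from 2 to 1, and Slob was also called without that of hour 3 or 7. The list call was lost without the array of hour 1, 10 or 12. It was also lost with quantile normalization, with median centring, with no filter on dim probe sets and with the actin ratio as a covariate, and with a stricter filter too few of its genes were left to test.

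Genes of phototransduction were not called as a list by camera (adjusted p = 0.0657), and their members went both ways. Adjusted over the list alone, 2 of 6 rose, trpl (adjusted p = 0.000351) and Arr1 (adjusted p = 0.00269). The scaffold gene inaD fell (adjusted p = 0.00231), with 274 at hour 1 and 209 at hour 12. Over all probe sets 0 of 6 passed. Arr2, trp and inaC did not pass either test, with changes of 0.03, -0.08 and 0.05. The fry test for change in either direction gave an adjusted p of 0.0118. For change in a shared direction fry gave an adjusted p of 0.74, and camera with an estimated correlation gave 0.729. The same 3 genes were called, with the same signs, without each array in turn.

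Mitochondrial and biosynthetic lists moved by small amounts. Oxidative phosphorylation had 50 of 56 slopes below 0 and a median change of -0.12 (camera, adjusted p = 0.000604; adjusted p = 0.814 with an estimated correlation). Mitochondrial ribosomal proteins had 54 of 57 slopes below 0 and a median of -0.11 (camera, adjusted p = 0.000783; adjusted p = 0.729 with an estimated correlation). In neither list did a gene pass over all probe sets or adjusted over the list alone. Examples are the complex I gene ND-B22 with -0.22 ± 0.09 and the ribosomal gene mRpL40 with -0.20 ± 0.07. The array of hour 10 was the lowest for both lists, at -0.24 and -0.17 relative to each gene's mean. Without it their medians were -0.07 and -0.07 and neither was called. Oxidative phosphorylation was not called without the array of hour 1 either.

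Fatty acid synthesis had 8 of 10 slopes above 0 and a median of 0.12 (camera, adjusted p = 0.0023; adjusted p = 0.729 with an estimated correlation). 0 of 10 genes passed over all probe sets or adjusted over the list alone. The desaturase gene Desat1 had 361.7 at hour 1, 269.8 at hour 2 and 517.3 at hour 12, and the fatty acid synthase gene FASN1 had 384.2, 232.4 and 429.3. The list median was 0.07 without the array of hour 12 and 0.21 without that of hour 1. DNA replication and cell cycle genes had 5 of 6 slopes below 0 and a median of -0.19 (camera, adjusted p = 0.0296; adjusted p = 0.729 with an estimated correlation). 0 of 6 passed over all probe sets or over the list alone. The cyclin gene CycB had 840.5 at hour 1 and 657.9 at hour 12, and PCNA, the replication clamp gene, had 243.5 and 199.9. That list was not called without the array of hour 1, 10 or 12, without those of hours 3 and 9 or of hours 3, 7 and 9, with no filter on dim probe sets or with a stricter one.

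Lists on feeding and insulin were among those not called. The insulin and TOR pathway had 10 tested genes, 6 with positive slopes, and a median of 0.07 (camera, adjusted p = 0.211). The insulin receptor gene InR had 217.1 at hour 1 and 219.3 at hour 12. FOXO targets raised by starvation had a median of 0.000414 over 5 genes (adjusted p = 0.7). Pepck1, a gluconeogenic gene, had a change of -0.29 ± 0.24 (limma, adjusted p = 0.937) and the lipase gene bmm had 0.000414 ± 0.12 (limma, adjusted p = 0.9995). The proton pump V-ATPase and hemocyte lists each had a camera adjusted p of 0.0657, with medians of 0.05 and -0.38. The hemocyte list was called with quantile normalization, with median centring, with a stricter filter on dim probe sets, with the actin ratio as a covariate and without the array of hour 1. The V-ATPase list was called with quantile normalization and without the array of hour 2 or 10. Leaving out single arrays also called phototransduction (hour 1 or 9), translation factors (hour 1 or 10), heat shock (hour 2) and proteasome (hour 12). The hemocyte members Col4a1, vkg, Hml and PPO2 had changes of -0.56, -0.52, -0.24 and 0.01. Heat shock, adult cuticle, translation factors, ribosome biogenesis, detoxification, lipid breakdown, proteasome and carbohydrate digestion had adjusted p-values between 0.22 and 0.372. Autophagy, neuron, gluconeogenesis and trehalose, midgut serine proteases, muscle, cytosolic ribosomal proteins, antimicrobial peptides, glycolysis, peptidoglycan recognition and testis had adjusted p-values between 0.679 and 0.853. Dawn-phase clock genes, Turandot peptides, accessory gland genes and larval serum proteins had 1, 0, 0 and 2 tested genes and were too few.

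The values of some lists on single arrays were as follows. Testis genes averaged 1.04 above each gene's mean at hour 7 and between -0.17 and -0.02 on the other 9 arrays. Mst84Dd, a sperm tail gene, had 753.8 at hour 7 and a median of 123 elsewhere, while aly and sa, also in the list, stood at 1.04-fold and 0.989-fold of theirs. The 4 tested antimicrobial peptide genes averaged 1.15 at hour 9 and 0.71 at hour 2, and at most 0.285 on the other 8 arrays. The hour 9 mean rested on the diptericin gene DptB and the metchnikowin gene Mtk, which stood 7.89-fold and 5.3-fold above the median of the other arrays, while the drosomycin gene Drs stood 1.31-fold and the defensin gene Def 1.08-fold above it. Over all 6 genes of the list, dim ones included, the median deviation was 0.863 at hour 2, 0.51 at hour 6 and 0.441 at hour 9. DptB had 1531 at hour 9 and 1041 at hour 2, against 178.1 at hour 12. The neuron list averaged -0.265 at hour 9. The muscle list averaged -0.265 at hour 9 and -0.234 at hour 10.

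**Figure D2:**
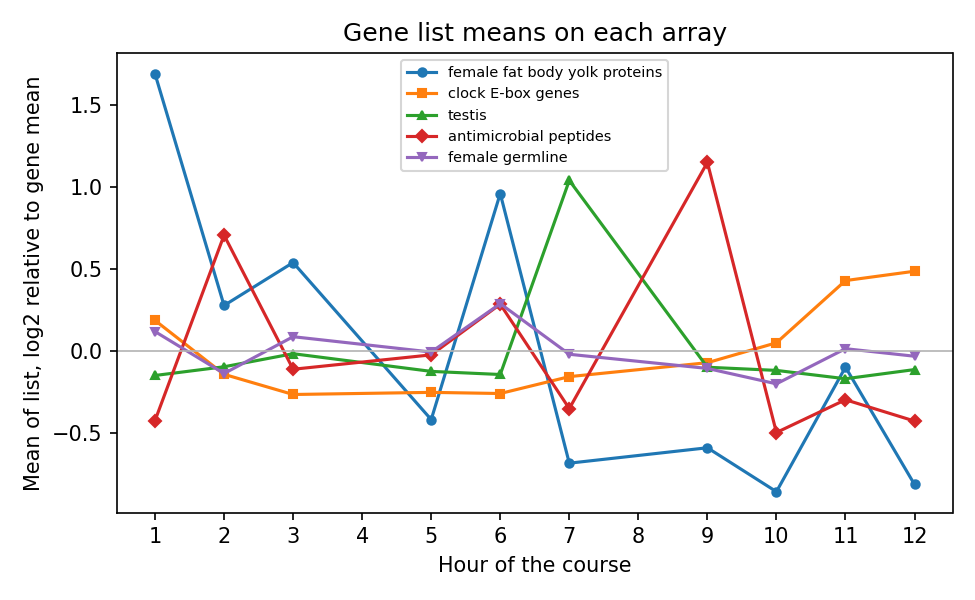
Mean log2 intensity of the tested genes of 5 lists on each array, relative to each gene's mean over the 10 arrays, against the hour; lines join the arrays of a list. The yolk protein list stands at 1.69 at hour 1 and 0.96 at hour 6, the testis list at 1.04 at hour 7 and the antimicrobial peptide list at 1.15 at hour 9, where DptB and Mtk were high.

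Whether arrays close in time were alike was asked over all tested probe sets. Over 45 pairs of arrays the distance between arrays and the gap in hours had a Pearson r of -0.02 (permutation test of the hours, 100000 draws, two-sided p = 0.91). The hour 3 array had the lowest mean correlation with the others, 0.929, and the other 9 lay between 0.967 and 0.978. On it 264 probe sets lay over 2-fold above the median of the other arrays and 1 lay over 2-fold below. Hours 9 and 7 followed with 27 and 15 above. Without the arrays of hours 3 and 9, a choice made after the data were seen, the counts were 1 for the trend and 0 for later against earlier hours. They were 1 and 0 without hours 3, 7 and 9. The 3' to 5' ratio of the actin control probe sets had a Pearson r of -0.05 with the hour (permutation p = 0.888, adjusted p = 0.888; Spearman rho -0.04, permutation p = 0.92, adjusted p = 0.92; r = -0.21 without hours 1 and 12, the 2 farthest from the median hour). The GAPDH ratio had an r of 0.215 (permutation p = 0.562, adjusted p = 0.888; rho 0.13, permutation p = 0.732, adjusted p = 0.92; r = 0.29 without hours 1 and 12).

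**Figure D3:**
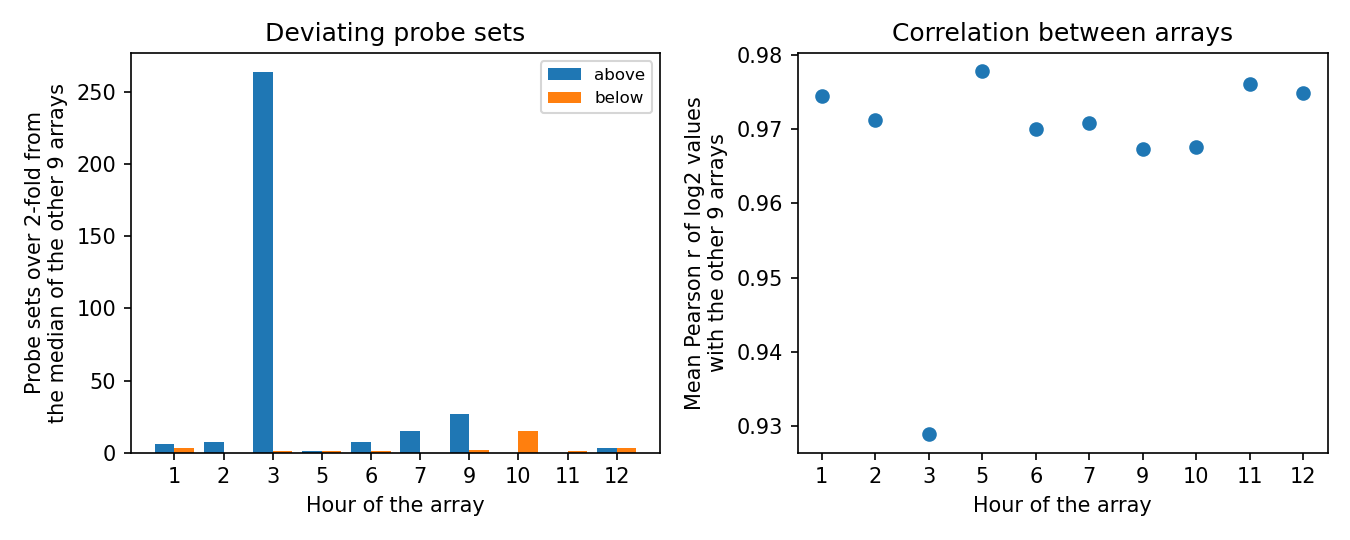
Left, the number of tested probe sets on each array that lie over 2-fold above or below the median of the other 9 arrays; right, the mean Pearson r of each array's log2 intensities with the other 9, on an axis that does not start at 0. The array of hour 3 has 264 probe sets above and a mean r of 0.929.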

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

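Each set of 10 array values was tested for a highest or lowest array set apart from the rest, by the gap to its nearest neighbour over the whole range (Dixon's test at its 95% limit). Of 91 sets, 16 passed. Chance would give about 4.55 if the values were normally distributed, which intensities and counts need not be. The excess over 4.55 is therefore not read as a result. The tests of array scaling, of 3' to 5' loss and of female tissue were chosen only after the result they bear on was seen.

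The hour 3 array passed in 8 of these. Its median intensity was 120 (others 111.1 to 115.6), its upper quartile 206.9 (others 182.4 to 195.2), its mean correlation 0.929 (others 0.967 to 0.978) and its count of raised probe sets 264 (others 0 to 27). The adult cuticle list stood at 0.13 there (others -0.04 to 0.03). Jhbp13 had 484.6 there (others 192.4 to 325.9), RnrL had 133.6 (others 109.4 to 121.7) and mRpL23 had 325.5 (others 188.8 to 241.9). The raised probe sets included CG18536 (3641), Capa (1934), ppan (645.9) and EDTP (1958).

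Array scaling as the whole cause is argued against, since 152 probe sets were still raised at hour 3 after quantile normalization and at most 31 on any other array. For a raised background the dimmest probe sets were examined, those in the lowest 10% of the table. Their median deviation at hour 3 was 0.0321 (SD of the other arrays 0.0427). The authors' normalization curve could have removed such a shift from dim probe sets, so this value cannot decide. The raised probe sets were not especially dim, with a median of 176 over the other arrays against 168 for all tested probe sets. A response that passed through the neighbouring hours is argued against by a median deviation of these probe sets of 0.0558 at hour 2 and 0.0514 at hour 5. Loss of the 5' end stays open. The hour 3 array's 3' to 5' ratio lay 1.73 SD above the mean of the other 9 arrays for actin and at -0.222 SD for GAPDH, and neither value decides. The hour 6 array had higher log2 ratios for actin and GAPDH, 1.357 and 1.818 against 1.336 and 1.781 at hour 3. It had 7 raised probe sets, but it is 1 array. A difference in the flies pooled at hour 3, and a response confined to that hour, stay open and were not tested.

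The testis list stood at 1.04 at hour 7 (others -0.17 to -0.02), where 13 of its 18 genes had their highest value and 10 lay over 2-fold above the other arrays, but not aly (1.04-fold), sa (0.989-fold), can (0.929-fold) or fzo (0.836-fold). A candidate explanation is that male flies entered the hour 7 pool, and the accessory gland genes, a second male tissue too dim for the main tests, were examined for it. Their median deviation at hour 7 was 1.27 on the log2 scale and at most 0.13 on any other array, and 13 of 13 had their highest value at hour 7. Acp95EF had 395.9 there against a median of 38.9, Acp36DE 188.7 against 68.5, and the testis gene dj 130 against 12.5. The medians of 38.9 and 12.5 are under the floor. Array scaling is argued against by a testis mean of 1.06 at hour 7 after quantile normalization, with at most -0.04 elsewhere; the labels used here do not give the sex of the flies, so this stays a hypothesis.

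Yp1 and Yp2 stood apart at hour 1, with 1332 (others 161.7 to 734.7) and 1135 (others 166 to 509.3), but the fall did not rest on that array alone, since the yolk list's median change was -1.26 without it and -1.84 with it. Less female or ovarian tissue in later pools may be the cause and stays open, because the tested eggshell and germline genes were split. Of 16, 8 varied 1.5-fold or more over the arrays. Choosing by range sets aside genes that hardly changed, so the values of these 8 cannot decide the question. Over all 8 eggshell and all 8 germline genes the median changes were -0.0144 and -0.05 on the log2 scale. As a percent of each gene's own range, the median change of the 8 that varied was -22.8 (quartiles -61.8 and -4.6) against -68.8 for the yolk proteins. Among them were -71.7 for Vm26Aa, -71.5 for exu and -58.6 for Vm34Ca but -8.24 for orb and 12.3 for osk. All 3 yolk genes had their highest value at hour 1, as did 2 of 13 germline and 3 of 15 eggshell genes, while 7 germline genes and 1 eggshell gene had theirs at hour 6, where the yolk list stood at 0.96. A response to the diet or the time of day stays open and untested.

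The other results set apart were these. At hour 10, 15 probe sets lay over 2-fold below the other arrays (others 0 to 3). The cytosolic ribosomal protein list stood at -0.10 there (others -0.03 to 0.05) and the lipid breakdown list at -0.14 (others -0.02 to 0.10). The neuron list stood at -0.265 at hour 9 (others -0.01 to 0.11). The 18S ribosomal RNA control had 1248 at hour 6 (others 90.3 to 501.3).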

How the results depend on the processing

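The tests without the arrays of hours 3 and 9, and of 3, 7 and 9, were chosen after the result was seen. The trend count of 4 was 1 with an offset, 0 with no filter, 0 with the actin ratio, 2 with array order, 0 with least squares, 0 with the rank correlation, 1 without hours 3 and 9 and 1 without hours 3, 7 and 9. Leaving out each array gave 0 to 2. With quantile normalization it was 5, with 3 higher and 2 lower, where trpl and CG17108 gained the call and t lost it. After median centring it was 3, with 2 higher and 1 lower. The later against earlier count of 1 was 3 with quantile normalization, 2 with median centring, 3 with the stricter filter, 2 with 1 probe set per gene, and 0 with no filter, with the actin ratio, with the splits after hours 5 and 7 and without hours 3 and 9 or hours 3, 7 and 9. Leaving out each array gave 0 to 2. The smooth count of 0 was 4 with a quadratic curve and 6 with a cosine and sine. The 7 lists were 0 with the estimated correlation and 0 with fry, and 5 to 9 leaving out each array. The break scan's highest count of 1 was 3 with quantile normalization. The array distance stayed short of the threshold throughout, between -0.11 and 0.18 leaving out each array, as did the control ratios.

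No gene or list past its threshold reversed, though the clock-controlled output median was 0 with no filter and genes near 0, such as per and cry, changed sign. Over all alternatives for single genes, 54 values lost the call, 2 gained one and 19 moved by more than 1 SE without a call. The other 951 did neither. Only Pdh, t, vri and Usp8 had a trend call to lose, so the 54 all belong to them. The 951 include the values of genes not called in the main fit, so these counts give no rate of loss. For single lists, 31 lost the call and 136 kept it. Members called over the list alone were 3 of 3 for yolk proteins and 3 of 6 for phototransduction whichever single array was left out. The smooth count for clock genes was 4 without hour 10, 3 without hour 1 and 2 without each other hour. The causes were not tested, except that leaving out arrays lowers the number fitted. The smallest adjusted p of the trend ranged from 0.00678 to 0.792 over the alternatives. Transcripts near the background were left out by the filter or held at the floor, so their changes were not resolved here.

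Chance was weighed by refitting. Of 100 orders of the hours, the real one among them, 1 gave as many as 4 trend calls and the highest other gave 1. Of 100 splits into 5 and 5, drawn from 126, 2 gave at least 1 call and the highest other gave 2. Each of these shares is under 0.05 taken alone. Several counts were examined without allowance for that, so chance is not excluded. For the lists the share was larger, since 18 of 100 orders gave at least 7 lists, with 12 in the highest other and a median of 4.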

Other observations

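The genes raised at hour 9 were examined after their values were seen. Antimicrobial and immune-induced peptide genes were among the 27 probe sets over 2-fold above the other arrays. The most raised, at 32.5-fold, and the next, at 12.3-fold, had no single named gene here. The 27 also included Rab10, with 3998 against 1181, Rgk2, with 462.8 against 95.2, and rasp, with 989.4 against 372.1. DptB had 1531 at hour 9 against a median of 194 elsewhere, and the metchnikowin gene Mtk had 1420 against 267.8. The bomanin family genes BomBc3, BomS2, BomBc2 and BomS5 had 655.7, 527.5, 727.8 and 874.1, against medians of 172.7, 149.4, 271.7 and 398.6. Bbd, named bombardier and outside that family, had 891.7 against 190.8. The iron-binding transferrin gene Tsf1 had 415.1 against 202.7. The peptidoglycan recognition gene PGRP-SB1 had 292.9 at hour 9 and 267.8 at hour 2. Drosomycin, Drs, was bright on every array, from 3778 to 5036. Hour 2 had 1041 for DptB, 544.4 for Mtk and 1144 for the defensin gene Def.

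Hours 3 and 9 shared 4 of their raised probe sets, 264 and 27 in number, where independent sets of those sizes would share 0.85. They were EDTP, CG18536, CG10086 and CG7382. EDTP, a phosphoinositide phosphatase gene, had 1958 at hour 3 and 953 at hour 9, with a median of 271.2 on the other 8 arrays. CG10086 had 916.5 and 1257 against 171.9. The count was not tested.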
